A study of Caenorhabditis elegans with 27 samples.

How the data were processed

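The measurements are RNA sequencing of whole animals in 27 libraries, 3 for each of 9 groups formed by 3 strains and 3 exposures. Per the labels' protocols, polyadenylated RNA was prepared with an unstranded kit and sequenced on an Illumina NovaSeq. The authors deposited a single table of FPKM values, fragments scaled to transcript length and library total, with a row for each gene and a column for each library. Per the submitters' processing notes, CASAVA, fastp, HISAT2 and StringTie were used and the genome build was WBcel235. Their versions and settings, and which of these tools did what, are not given in the sources used here. Because the kit does not mark strand, reads of overlapping or antisense genes cannot be told apart. Reads of near-identical paralogs, such as major sperm protein, histone and cyp-35A genes or the 2 genes named clec-209, may have been split among them. No identifier of the table names a human transgene, so the strain labels, on which every comparison between strains rests, could not be checked against the transgenes.

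Every library was assigned to its group by its label, and all columns of the table were used. Gene names and coordinates came from the WBcel235 annotation, in which 46180 of 46589 identifiers were matched and 409 were not. Of the genes, 19660 were at 0 in every library. The FPKM are whole multiples of the value of 1 fragment: for 100.0% of the 26929 genes above 0, a length could be found at which every library holds a whole number of fragments within 1e-06. That length equalled the annotated one for 33.2% of the genes. The recovered fragments gave the depth of each library, and a library-specific factor of 0.973 to 1.04, whose origin is not given in the sources used here, separates the total used for scaling from the sum of fragments. An FPKM of 1 corresponded to 23.0 fragments for the median gene in the median library, so that levels far under 1 rest on single fragments. The list medians given here use the values as they stand. For comparison they were also taken with a floor of 3 fragments over a group, for members at 0 in all its libraries. In the 12 contrasts between 2 groups this applied to 26 of 504 pairs of list and contrast, and the largest shift of a median was 0.0405.

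Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 libraries were kept, 16784 in all, of which 14418 are protein-coding, 942 piRNA, 542 pseudogenes, 480 ncRNA and 197 not matched to the annotation. A mean was fitted for each of the 9 groups in a single model, so that all groups share an estimate of the spread, with moderated variances (trend and robust options). The 16 contrasts were each dose against DMSO and against each other within strains, the strains against each other in DMSO, and the difference of the BaP response between each modified strain and the control strain. P-values were adjusted by Benjamini and Hochberg within each contrast, and genes under 0.05 were called. The 5 main contrasts were 640 µM against DMSO in each strain and each modified strain against the control strain in DMSO.

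Of 43 gene lists, 42 were tested with camera in the 16 contrasts, with a preset correlation of 0.01 between genes and adjustment within each contrast. The lists cover detoxification (cytochromes P450, their partners and epoxide hydrolases, glutathione S-transferases, UDP-glucuronosyltransferases, short-chain dehydrogenases, ABC transporters, heme transport, xenobiotic receptors), stress (SKN-1 targets, antioxidant enzymes, heat shock, unfolded protein responses, DNA repair, metals, DAF-16 targets), immunity (C-type lectins, lysozymes and antimicrobial peptides, infection response), lipids (fatty acid synthesis, beta-oxidation, lipases, lipid-binding proteins, vitellogenins), cuticle (collagens, molting), germline (sperm, oocyte and eggshell, mitosis and meiosis, Argonautes), general functions (ribosomal proteins, nuclear oxidative phosphorylation, histones, housekeeping) and tissues (neuropeptides, neuron, body wall muscle, pharynx, intestine, hypodermis, coelomocytes). The list of genes of the mitochondrial genome was not tested, since none of its names matched an identifier. Taking its members by chromosome was tried after the data had been seen and was not kept. For each list, members were also adjusted over the list alone.

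The genes named in the text follow a rule set before the data were examined, as were the tests, the lists and the alternatives unless said otherwise. In each main contrast it takes the 6 largest rises and 6 largest falls among called genes with a name of the usual form, no overlap between the groups' libraries and a mean FPKM of at least 5 in the higher group. From each list that was called or had at least 3 called members, it takes the 2 members with the smallest adjusted p and the 1 with the largest fold. It adds 8 fixed genes: ahr-1, cyp-35A2, cyp-35A5, gst-4, ugt-25, hsp-4, cep-1 and emb-8. In the other contrasts it takes 3 rises and 3 falls. For a difference of responses, the criteria of overlap and level were applied to the exposed and DMSO libraries of the modified strain, a reading of the rule made once the data were seen. The text gives the members that matter most, and genes named outside the rule are said to be so.

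The alternatives set beforehand were a pseudocount of 0.1, no filter, a stricter filter on a mean FPKM of 5, TPM, median-of-ratios and quantile scaling, only the compared groups in the fit, variances without trend and robust options, sample weights (arrayWeights), the replicate number as a block, and each library left out in turn. For lists they were camera with an estimated correlation and fry. Chosen after seeing the data were limma voom on the recovered fragments and a restriction to protein-coding genes. Fits were tested on simulated data with 200 changed genes among 15975. For 640 µM against DMSO in the control strain, 86% of genes changed 1.5-fold and 88% of those changed 2-fold were called, with 10 false calls. With voom the values were 91%, 89% and 7. For the other response of the CYP1A1 strain at 640 µM they were 70%, 83% and 11. A raised list was called by camera. The simulated genes varied independently with a single setting of spread, so this run cannot check the preset correlation. The real contrasts each called a larger share of genes, so the simulated rates need not hold for them. Gene-level correlations between contrasts that share controls were compared with 100 simulations of unchanged groups. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.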

Results

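RNA sequencing measured the polyadenylated transcripts of whole Caenorhabditis elegans exposed to benzo[a]pyrene (BaP), a polycyclic aromatic hydrocarbon that mammalian cytochromes P450 and epoxide hydrolase convert to DNA-binding metabolites. Synchronized larvae were kept for 48 h at 20 °C, from the first larval stage to the L4 stage, with dimethyl sulfoxide (DMSO) alone or with BaP at 40 µM or 640 µM in both the agar and the bacterial lawn. The 3 strains were an unmodified background strain (control strain), a strain modified to express human CYP1A1 and the epoxide hydrolase EPHX (CYP1A1 strain) and a strain modified to express human CYP1A2 and EPHX (CYP1A2 strain). Each of the 9 combinations of strain and exposure had 3 libraries, so that n = 3 holds for every group mean. Fragments assigned to genes per library ranged from 17530275 in replicate 2 of the control strain at 40 µM to 29890843 in replicate 2 of the control strain at 640 µM, with a median of 20657918. Levels are given as mean FPKM ± SD. Changes are differences of log2(FPKM + 1) ± standard error, a scale that understates the change of genes at low levels. Adjusted p-values come from limma. Of 46589 genes in the table, 16784 passed the filter on low values and were tested. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

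The DMSO and 640 µM libraries separated along the first principal component, which held 51.6% of the variance. The next component held 12.5%. The correlation of log2(FPKM + 1) across genes within a group was at least 0.979, with a median of 0.983, and between groups it ranged from 0.872 to 0.981. No libraries were identical, and replicate pairs differed by more than sampling noise, with a mean chi-square per gene of 1.94 to 5.38. Replicate 3 stood apart in both modified strains at 640 µM. In the CYP1A1 strain it had chi-squares of 5.38 and 3.55 against 2.67 between the other two and a first component score of 35 against 52.3 and 50, and without it 9444 genes changed against 9832 with it. For the CYP1A2 strain the chi-squares were 3.90 and 3.97 against 2.31 and the second component scores -47.2 against -32.0 and -31.1, and without it 8877 genes changed against 9553. For group means that move by more than 1.5 times without 1 library, the mean without it is given beside them. The aryl hydrocarbon receptor gene ahr-1 stayed under the filter in these whole animals, with group means of 0.329 to 0.632 FPKM and 6 to 37 fragments per library. Its response was therefore not tested.

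**Figure D1:**
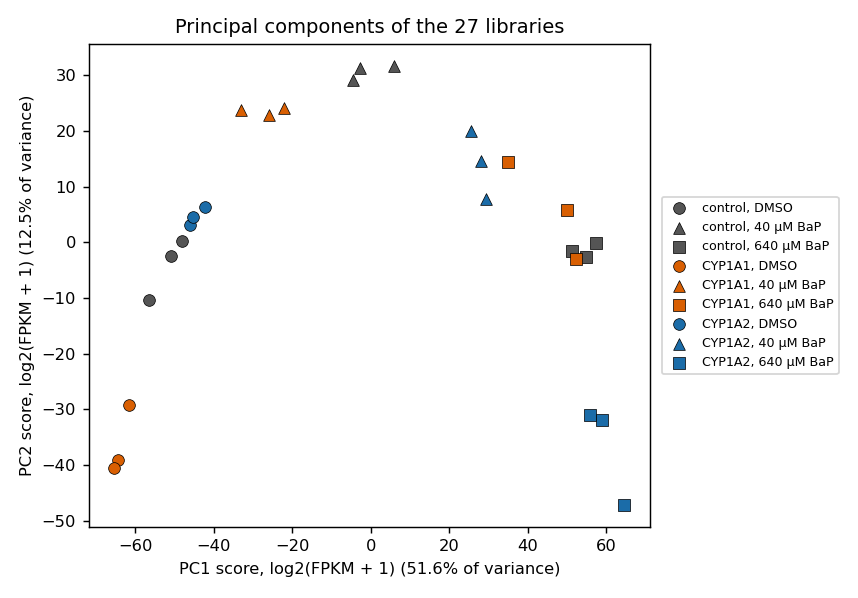
Principal components of log2(FPKM + 1) over the tested genes, each point a library, with the exposure shown by the symbol and the strain by the colour. The axes give the scores on the first component (51.6% of the variance) and the second (12.5%). The DMSO libraries score from -65.4 to -42.2 on the first component and the 640 µM libraries from 35 to 64.6.

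The first comparison asked how unmodified animals responded to the high dose. In the control strain, 640 µM BaP changed 9831 genes against DMSO, 4795 higher and 5036 lower, of which 1062 rose and 1278 fell at least 2-fold. The largest rise on the log2(FPKM + 1) scale was that of irg-5 (F35E12.5, chromosome V, 13737010 to 13738474 in WBcel235), a gene induced by bacterial infection, which went from 2.97 ± 0.0866 to 5028 ± 200.1 FPKM (log2 change 10.31 ± 0.09, adjusted p = 7.73e-27). Another infection response gene, irg-4 (F08G5.6), rose from 7.66 ± 1.13 to 769 ± 2.02 FPKM. The gene clec-206 (F59A7.1), which encodes a C-type lectin domain protein, rose from 0.256 ± 0.202 (0.143 without replicate 2) to 181 ± 11.3. Xenobiotic-inducible cytochromes P450 followed. The transcript of cyp-35C1 (C06B3.3, chromosome V, 13896663 to 13898487) rose from 9.52 ± 0.567 to 743 ± 49.7 FPKM (log2 change 6.14 ± 0.10, adjusted p = 2.86e-22). Levels of cyp-35A3 (K09D9.2) went from 1.17 ± 0.0760 to 241 ± 27.3, those of cyp-35A5 (K07C6.5) from 3.90 ± 0.749 to 206 ± 20.6 and those of cyp-35A2 (C03G6.15) from 24.7 ± 0.272 to 317 ± 19.7. Transcripts of cyp-35A1 (C03G6.14) stood at 0.0113 ± 0.0196 FPKM in DMSO (0 without replicate 1) and at 97.0 ± 5.01 with BaP. The cyp-35A genes are close paralogs, and how reads were divided among them is uncertain.

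Gene lists for detoxification, stress, tissues and reproduction had been fixed before the data were examined, and each was compared with all other genes by camera. A second adjusted p-value, with the correlation between list members estimated from the libraries, is given beside each call that it does not keep. Counts adjusted over the list alone, with the higher members first, are given where they differ from those over all genes. Of the 54 measured cytochromes P450, 35 rose and 8 fell (median log2 change 0.47, camera adjusted p = 5.56e-07). UDP-glucuronosyltransferases are phase II enzymes that attach sugars to hydroxylated compounds. Of 60 measured, 40 rose and 12 fell (43 and 12 adjusted over the list alone), with a median change of 0.76 (adjusted p = 3.04e-10). Here ugt-8 (H23N18.3) rose from 5.92 ± 0.563 to 201 ± 9.91 FPKM, ugt-16 (ZC443.6) from 4.91 ± 0.475 to 199.9 ± 2.55, and ugt-25 (C10H11.3) from 20.4 ± 2.14 to 58.7 ± 0.499. The list of P450 partners and worm epoxide hydrolases rose as well, with 5 of 6 members higher (median 0.98, adjusted p = 1.40e-04). The cytochrome b5-like gene vem-1 (K07E3.8) went from 21 ± 0.883 to 155 ± 2.59 and the epoxide hydrolase gene ceeh-1 (K02F3.6) from 9.69 ± 0.161 to 32.3 ± 0.363. The P450 reductase gene emb-8 (K10D2.6) rose from 92.0 ± 1.30 to 125 ± 5.3 (log2 change 0.44 ± 0.04). Metal-responsive genes rose in 8 of 10 cases (adjusted p = 6.33e-04). The cadmium-responsive cdr-1 (F35E8.11) rose from 0.896 ± 0.294 to 34.7 ± 3.18 and the metallothionein mtl-1 (K11G9.6) from 6.89 ± 2.51 to 103.9 ± 1.80. Infection response genes numbered 15 higher and 4 lower of 25 (adjusted p = 0.00323). These 5 lists, from the P450s to the infection response, kept their call with an estimated correlation, and in this comparison no others did.

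Short-chain dehydrogenases were mostly higher, 20 against 4 lower of 29 (20 and 5 adjusted over the list alone, with camera adjusted p = 2.52e-04, and adjusted p = 0.0821 with an estimated correlation). Of these, dhs-23 (R08H2.1) rose from 0.345 ± 0.160 to 26.4 ± 1.14 FPKM. Heme transport genes rose in 6 of 8 (adjusted p = 0.00323, and adjusted p = 0.0821 with an estimated correlation). Xenobiotic receptor genes rose in 4 of 7 (6 and 0 adjusted over the list alone, with camera adjusted p = 0.0231, and adjusted p = 0.0979 with an estimated correlation), and nhr-176 (F14H3.11) went from 7.07 ± 0.902 to 18.6 ± 1.74. Glutathione S-transferases went both ways, 18 higher and 8 lower of 39, without a list call (adjusted p = 0.0832). Here gst-5 (R03D7.6) rose from 25.4 ± 1.36 to 460.3 ± 17.9, while gst-10 (Y45G12C.2) fell from 167 ± 4.77 to 62.7 ± 3.80. A widely used reporter of oxidative stress, gst-4 (K08F4.7), fell from 80.9 ± 2.46 to 42.3 ± 2.63 (log2 change -0.92 ± 0.08, adjusted p = 4.31e-09). Not called were the SKN-1 target list (7 higher, 4 lower of 14, adjusted p = 0.363), antioxidant enzymes (8 and 1 of 22, adjusted p = 0.0766) and ABC transporters (23 and 17 of 49, adjusted p = 0.216).

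Cytosolic heat shock genes fell as a list, 12 lower and 1 higher of 15 (median -0.32, adjusted p = 0.00378, and adjusted p = 0.0821 with an estimated correlation). The heat-inducible hsp-70 (C12C8.1) fell from 6.18 ± 0.166 to 0.538 ± 0.223 FPKM and the chaperone gene hsp-110 (C30C11.4) from 169 ± 4.22 to 135 ± 2.71. Genes of the endoplasmic reticulum unfolded protein response were higher in 14 of 19 cases (median 0.38, adjusted p = 3.56e-04, and adjusted p = 0.192 with an estimated correlation). They included calreticulin crt-1 (Y38A10A.5, from 1361 ± 9.53 to 2232 ± 50.5) and endoplasmin enpl-1 (T05E11.3, from 258 ± 4.36 to 446 ± 14.8). The BiP gene hsp-4 (F43E2.8) measured 224 ± 2.82 with BaP and 218 ± 12 without (adjusted p = 0.499). The mitochondrial unfolded protein response list was not called (5 higher and 2 lower of 10, adjusted p = 0.370). DNA damage response and repair genes fell by small amounts, 29 lower and 1 higher of 52 (2 and 29 adjusted over the list alone), with a median of -0.19 (adjusted p = 6.61e-04, and adjusted p = 0.353 with an estimated correlation). Of these, the ribonucleotide reductase gene rnr-2 (C03C10.3) fell from 61.3 ± 1.61 to 37.5 ± 1.92. The p53 homologue cep-1 (F52B5.5) fell from 14.4 ± 0.545 to 12.2 ± 0.471 (log2 change -0.22 ± 0.07), a call that ended under quantile normalization and without DMSO replicate 3.

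The lowest list medians in this comparison were those of cuticle and reproductive genes. Collagens were lower in 91 and higher in 35 of 139 cases (35 and 92 adjusted over the list alone, with median -1.19, adjusted p = 2.80e-07, and adjusted p = 0.197 with an estimated correlation). The adult collagen col-19 (ZK1193.1, chromosome X, 421707 to 422691) stood at 0.0279 ± 0.0261 FPKM with BaP (0.0161 without replicate 1) against 124 ± 32.8 in DMSO. Other collagens with low levels at 640 µM were col-88 (W05G11.3) at 0.136 ± 0.0832 against 496 ± 99.6 and col-124 (C24F3.6) at 6.76 ± 0.727 against 289 ± 67.6. All 6 vitellogenins, the yolk protein genes of the intestine, fell (median -3.32, adjusted p = 8.24e-06, and adjusted p = 0.0821 with an estimated correlation). Transcripts of vit-6 (K07H8.6, chromosome IV, 8261157 to 8266459) went from 125 ± 36.7 to 3.74 ± 0.202 FPKM. Oocyte and eggshell genes fell in 26 of 27 cases (median -1.95, adjusted p = 4.73e-17, and adjusted p = 0.0773 with an estimated correlation). Needed for the eggshell's permeability barrier, perm-4 (C44B12.5) fell from 102 ± 11.9 to 3.76 ± 1.44, and the eggshell proteoglycan gene cpg-2 (B0280.5) from 166 ± 17.2 to 25.4 ± 0.833. All 48 measured genes of the major sperm protein list fell (median -1.50, adjusted p = 3.78e-17, and adjusted p = 0.214 with an estimated correlation). Reads from near-identical copies may have been shared among them. Of these, msd-1 (F44D12.3) went from 62.9 ± 2.44 to 19.9 ± 1.30. Genes expressed in germ cells of all stages had a median closer to 0, 17 lower and 2 higher of 29 (median -0.18, adjusted p = 0.0154, and adjusted p = 0.538 with an estimated correlation). The translational repressor gld-1 (T23G11.3) fell from 217 ± 10.3 to 119.5 ± 3.98. By contrast fog-3 (C03C11.2), which commits germ cells to the sperm fate, rose from 4.3 ± 0.633 to 14.5 ± 1.65.

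Several lists of general cell function and tissue identity moved by smaller amounts. Ribosomal protein genes rose in 56 of 78 cases and fell in 3 (57 and 3 adjusted over the list alone, with median 0.19, adjusted p = 2.55e-07, and adjusted p = 0.383 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 31 of 37 (median 0.26, adjusted p = 3.69e-06, and adjusted p = 0.208 with an estimated correlation). Neuropeptide genes were higher in 82 and lower in 4 of 115 cases (85 and 4 adjusted over the list alone, with median 0.60, adjusted p = 6.06e-09, and adjusted p = 0.0979 with an estimated correlation). The insulin-like ins-33 (W09C5.4) rose from 9.05 ± 1.48 to 33.2 ± 1.84 FPKM. Pan-neuronal genes rose in 12 of 16 (13 and 0 adjusted over the list alone, with median 0.44, adjusted p = 1.69e-04, and adjusted p = 0.0821 with an estimated correlation). Pharynx genes rose in 9 of 14 (adjusted p = 0.0463, and adjusted p = 0.538 with an estimated correlation). Molting genes (11 higher, 7 lower of 22, adjusted p = 0.670), body wall muscle (5 and 2 of 13, adjusted p = 0.363), intestine (8 and 5 of 16, adjusted p = 0.370) and hypodermis genes (3 and 5 of 13, adjusted p = 0.441) were not called. Coelomocyte genes (1 lower of 5, adjusted p = 0.969), histones (10 and 11 of 39, adjusted p = 0.798) and housekeeping genes (2 and 3 of 9, adjusted p = 0.798) were not called either. The reference genes gpd-1 (T09F3.3, from 68.4 ± 2.73 to 26.1 ± 1.94) and gpd-3 (K10B3.7, from 321 ± 17.8 to 537 ± 5.94) moved in opposite directions.

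**Figure D2:**
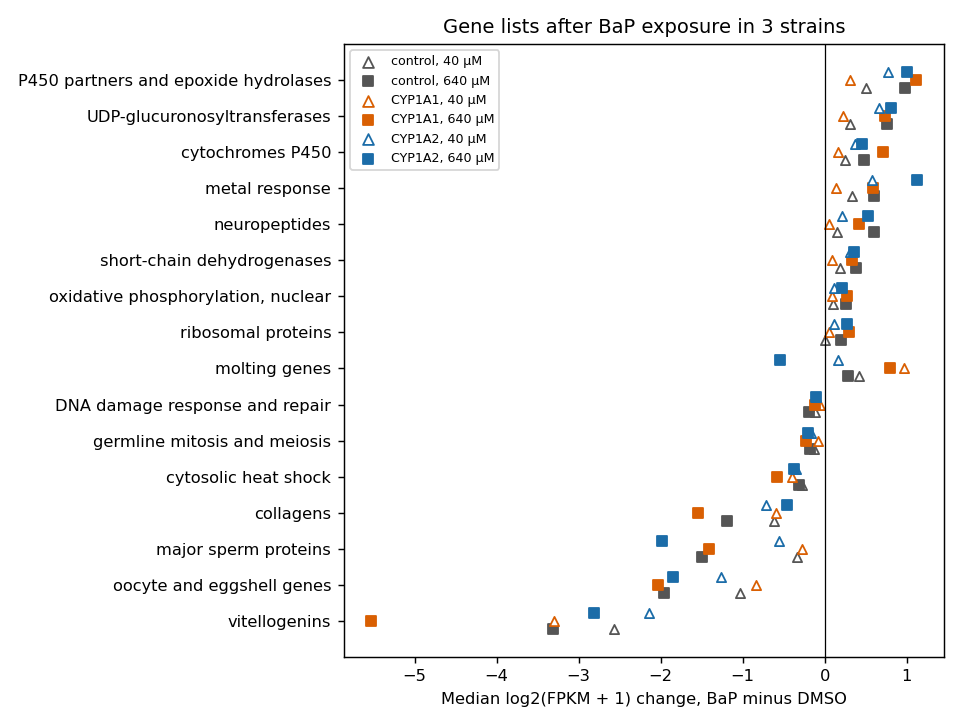
Median log2(FPKM + 1) change, BaP minus DMSO, of 16 fixed gene lists (x axis, log2 units), with 40 µM as open triangles, 640 µM as filled squares and a colour for each strain. The vitellogenin medians reach -3.32 in the control strain, -5.53 in the CYP1A1 strain and -2.81 in the CYP1A2 strain at 640 µM.

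The same exposure was then measured in each modified strain, to describe how animals with the human enzymes responded. In the CYP1A1 strain, 640 µM BaP changed 9832 genes, 4779 higher and 5053 lower. Among the rises, irg-5 went from 3.99 ± 0.10 to 5299 ± 463 FPKM (log2 change 10.05 ± 0.09) and cyp-35A3 from 0.677 ± 0.0517 to 245 ± 37.9 (7.18 ± 0.11). Further rises were those of cyp-35C1, from 12 ± 0.608 to 780.1 ± 109, and of ugt-8, from 5.84 ± 0.486 to 194 ± 22.6. Cytochromes P450 were higher in 31 and lower in 12 cases (33 and 12 adjusted over the list alone, with camera adjusted p = 2.67e-06). Glucuronosyltransferases were higher in 36 and lower in 15 (36 and 16 adjusted over the list alone, with camera adjusted p = 2.79e-06). All 6 P450 partners rose (adjusted p = 3.91e-05), and 7 of 10 metal-responsive genes rose (adjusted p = 0.00228). Among the fixed genes, cyp-35A2 went from 24.3 ± 0.236 to 383 ± 48.9, cyp-35A5 from 4.48 ± 0.666 to 219 ± 43.1, ugt-25 from 37.1 ± 2.09 to 61.6 ± 4.73 and emb-8 from 90.3 ± 2.14 to 127 ± 4.69. Heat shock genes fell in 13 of 15 cases (median -0.58, adjusted p = 2.40e-04), as did hsp-70, from 14.5 ± 1.67 to 1.62 ± 0.129. These 5 lists kept their call with an estimated correlation. Infection response genes were not called here (10 higher, 7 lower, adjusted p = 0.185), and their median of -0.01 and mean of 0.88 differed in sign.

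Vitellogenins fell in the CYP1A1 strain, vit-6 from 551 ± 73.1 to 4.49 ± 1.13 FPKM (list median -5.53, adjusted p = 4.94e-07, and adjusted p = 0.0628 with an estimated correlation). Collagens fell in 87 and rose in 33 cases (median -1.54, adjusted p = 5.00e-07, and adjusted p = 0.243 with an estimated correlation). With BaP, col-140 (F26F12.1) stood at 1.71 ± 2.66 against 858 ± 90.9 in DMSO and col-19 at 0.343 ± 0.357 against 473 ± 71.0. Without BaP replicate 3 the means with BaP were 0.181 for col-140 and 0.146 for col-19. Molting genes rose in 14 and fell in 7 of 22 cases (median 0.80, adjusted p = 0.0353, and adjusted p = 0.595 with an estimated correlation). The genes noah-1 (C34G6.6) and noah-2 (F52B11.3) encode zona pellucida domain proteins of the cuticle's precursor matrix. They rose from 23.7 ± 8.41 to 254 ± 24.9 and from 32.5 ± 11.6 to 343 ± 40.3, and the fibrillin-like fbn-1 (ZK783.1) from 1.0 ± 0.520 to 26.3 ± 5.09. Oocyte genes fell in 26 of 27 (median -2.03, adjusted p = 5.51e-16, and adjusted p = 0.0667 with an estimated correlation), perm-4 from 188 ± 21.1 to 6.22 ± 3.13. Sperm genes fell in 46 of 48 (median -1.41, adjusted p = 3.30e-15, and adjusted p = 0.267 with an estimated correlation). Ribosomal protein genes rose in 73 of 78 (adjusted p = 2.90e-13, and adjusted p = 0.245 with an estimated correlation). Short-chain dehydrogenases rose in 21 of 29 (adjusted p = 3.91e-05, and adjusted p = 0.0628 with an estimated correlation), and endoplasmic reticulum stress genes rose in 12 of 19 (adjusted p = 5.50e-04, and adjusted p = 0.243 with an estimated correlation). DNA repair genes were not called (6 higher, 20 lower, adjusted p = 0.235). Levels of hsp-4 were 245 ± 8.44 against 258 ± 4.39 (adjusted p = 0.149), and gst-4 fell from 63.1 ± 6.35 to 42.4 ± 4.20. The fall of cep-1, from 14.8 ± 1.54 to 12.4 ± 0.719, was a call that ended with only the compared groups in the fit, under quantile normalization, and without DMSO replicate 3 or BaP replicate 2. The median pharynx gene changed by 0.17 and the mean by -0.15, without a call (adjusted p = 0.968).

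In the CYP1A2 strain, 640 µM BaP changed 9553 genes, 4647 higher and 4906 lower. On the log2(FPKM + 1) scale irg-5 again had the largest rise, from 2.79 ± 0.675 to 4722 ± 231 FPKM (log2 change 10.30 ± 0.09, adjusted p = 7.89e-27). Rises followed for irg-4, from 5.42 ± 0.238 to 746 ± 81.5, cyp-35C1, from 15.2 ± 2.57 to 704 ± 2.82, and cyp-35A3, from 2.21 ± 0.424 to 196 ± 7.46. Cytochromes P450 rose in 32 and fell in 9 cases (33 and 10 adjusted over the list alone, with camera adjusted p = 5.33e-06), and glucuronosyltransferases rose in 42 and fell in 8 (adjusted p = 2.44e-12). All 6 P450 partners rose (adjusted p = 1.91e-05), as did 8 of 10 metal-responsive genes (adjusted p = 6.50e-05) and 15 of 25 infection response genes (16 and 2 adjusted over the list alone, with camera adjusted p = 1.24e-04). These 5 lists kept their call with an estimated correlation. Among the fixed genes, cyp-35A2 rose from 39.8 ± 4.39 to 301 ± 20.7, cyp-35A5 from 5.46 ± 0.733 to 163 ± 8.50, ugt-25 from 28 ± 1.47 to 82.0 ± 7.13 and emb-8 from 93.9 ± 4.34 to 123 ± 0.683. Levels of gst-4 fell from 64.2 ± 3.41 to 47.2 ± 0.880. The genes hsp-4 (from 254 ± 7.81 to 228 ± 12.8) and cep-1 (from 14.8 ± 0.560 to 12.5 ± 0.627) fell by calls that ended under quantile normalization. Glutathione S-transferases were called here by a narrow margin, 16 higher and 9 lower (19 and 11 adjusted over the list alone, with camera adjusted p = 0.0456, and adjusted p = 0.286 with an estimated correlation). Antioxidant enzymes rose in 12 of 22 (adjusted p = 0.00842, and adjusted p = 0.134 with an estimated correlation). Of these, sod-1 (C15F1.7, with 11.8% of its exon bases inside another gene) rose from 197 ± 11.3 to 319 ± 4.36.

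Molting and hypodermal transcripts fell in the CYP1A2 strain. Molting genes were lower in 13 and higher in 3 of 22 cases (median -0.55, adjusted p = 0.0101, and adjusted p = 0.423 with an estimated correlation), with mlt-10 (C09E8.3) falling from 308 ± 21.2 to 41.8 ± 6.78 FPKM. Hypodermis genes fell in 9 of 13 (2 and 10 adjusted over the list alone, with camera adjusted p = 0.00773, and adjusted p = 0.208 with an estimated correlation), with the hedgehog-related wrt-4 (ZK678.5) from 219 ± 11.8 to 8.89 ± 1.12. Collagens fell in 75 and rose in 37 cases (38 and 77 adjusted over the list alone, with median -0.45, adjusted p = 0.00340, and adjusted p = 0.423 with an estimated correlation). Of these, col-63 (ZK265.2) fell from 1907 ± 109 to 10.7 ± 11.9 (4.02 without replicate 2), whereas col-166 (T07H6.3) rose from 277 ± 10.9 to 1601 ± 131. The gene dao-4 (ZC373.6, chromosome X, 10075288 to 10076357) went from 371 ± 14.2 to 0.684 ± 0.278 FPKM. Vitellogenins all fell (median -2.81, adjusted p = 1.41e-05, and adjusted p = 0.0909 with an estimated correlation), vit-6 going from 115 ± 7.95 to 1.81 ± 0.434. All 27 oocyte genes fell (median -1.85, adjusted p = 1.34e-16, and adjusted p = 0.0630 with an estimated correlation), perm-4 going from 88.3 ± 6.57 to 0.807 ± 0.449. Of the 48 sperm genes, 47 fell (0 and 48 adjusted over the list alone, with median -1.98, adjusted p = 1.39e-20, and adjusted p = 0.154 with an estimated correlation). Heat shock genes fell in 11 of 15 (median -0.37, adjusted p = 0.00147, and adjusted p = 0.0630 with an estimated correlation), hsp-70 going from 8.47 ± 0.671 to 0.760 ± 0.252.

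**Figure D3:**
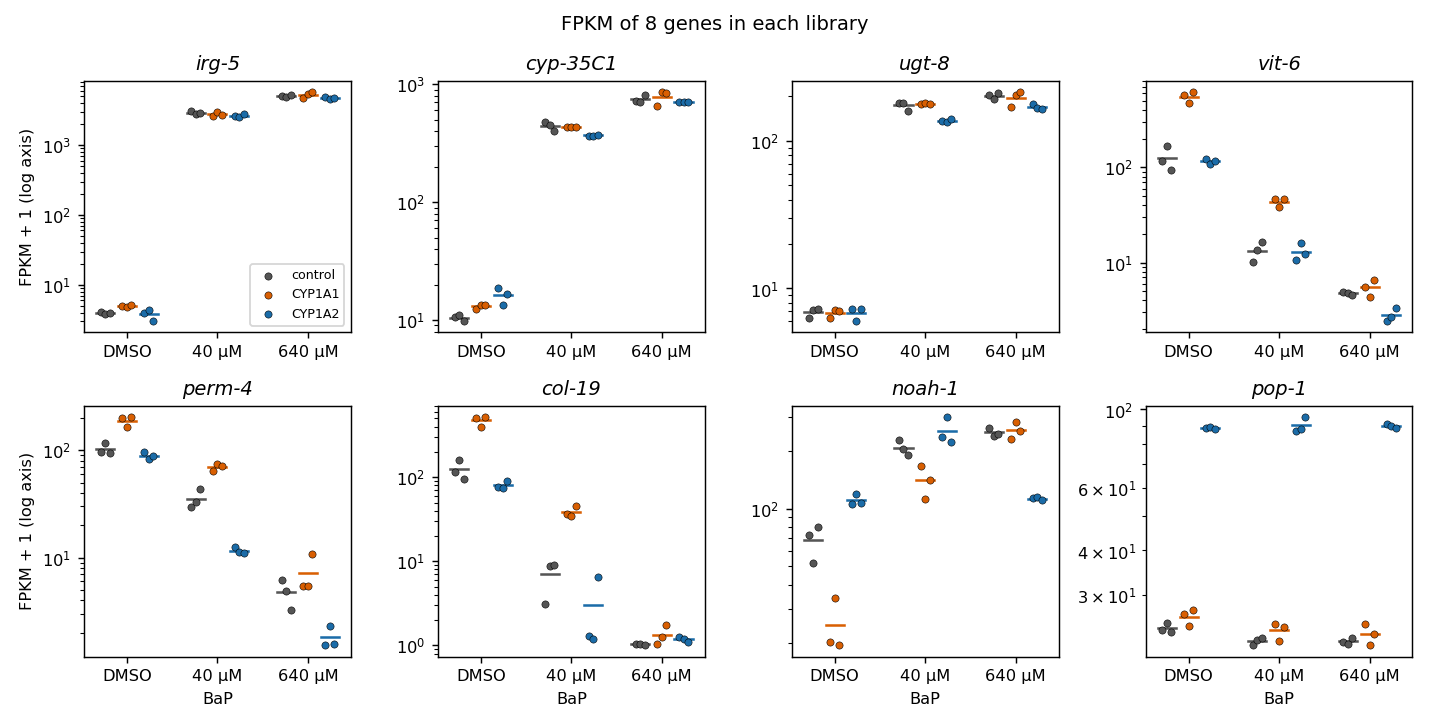
FPKM + 1 on a log axis for irg-5, cyp-35C1, ugt-8, vit-6, perm-4, col-19, noah-1 and pop-1 in each of the 27 libraries, grouped by strain and exposure, with a line at each group mean. At 640 µM the group means of irg-5 are 5028, 5299 and 4722 FPKM in the control, CYP1A1 and CYP1A2 strains.

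The comparison at the low dose asked whether the response was already present at 40 µM. It changed 5624 genes in the control strain (2813 higher, 2811 lower), 5373 in the CYP1A1 strain (2580 and 2793) and 6925 in the CYP1A2 strain (3104 and 3821). In the CYP1A2 strain 44.8% of the changed genes were higher, a share that other scalings moved by up to 8.57 percentage points. At this dose irg-5 rose by 9.52 ± 0.09, 9.11 ± 0.09 and 9.46 ± 0.09 on the log2 scale in the control, CYP1A1 and CYP1A2 strains. It reached 2918 ± 188, 2762 ± 177 and 2648 ± 135 FPKM. Falls at this dose included those of the collagens col-81 (F38A3.1, from 147 ± 48.4 to 6.85 ± 5.41) in the control strain, col-62 (C15A11.6, from 71.6 ± 20.6 to 1.74 ± 1.45) in the CYP1A1 strain and col-129 (M18.1, from 201 ± 20.5 to 5.69 ± 7.35) in the CYP1A2 strain. At 40 µM these means were 4.41 for col-81 without replicate 2, 0.931 for col-62 without replicate 3 and 1.44 for col-129 without replicate 3. Adult collagen col-19 fell to 6.0 FPKM in the control strain and 1.99 in the CYP1A2 strain (0.247 without replicate 3). Cytochromes P450 were called in the 3 strains, with 27, 23 and 29 members higher (27, 25 and 31 adjusted over the list alone, with camera adjusted p = 7.03e-08, 1.01e-04 and 3.62e-07), each also with an estimated correlation. Glucuronosyltransferases rose in 30, 29 and 35 cases (30, 30 and 35 adjusted over the list alone, with camera adjusted p = 2.59e-08, 1.01e-04 and 1.27e-10), the call in the CYP1A1 strain having adjusted p = 0.0787 with an estimated correlation. Heat shock genes fell in 10, 13 and 12 of 15 cases (12, 13 and 13 adjusted over the list alone, with camera adjusted p = 1.02e-04, 7.23e-09 and 4.34e-05), each also with an estimated correlation. All 6 vitellogenins fell in every strain (medians -2.57, -3.30 and -2.14, adjusted p = 3.51e-08, 1.04e-09 and 3.96e-06), the call in the CYP1A2 strain having adjusted p = 0.0881 with an estimated correlation. Oocyte genes fell in 26, 25 and 26 of 27 cases (26, 25 and 26 adjusted over the list alone, with medians -1.04, -0.84 and -1.26, adjusted p = 1.25e-20, 1.12e-13 and 8.39e-19), the call in the CYP1A1 strain having adjusted p = 0.138 with an estimated correlation. Sperm genes fell in 15, 6 and 45 of 48 cases (1, 0 and 45 adjusted over the list alone, with camera adjusted p = 6.55e-05, 0.00166 and 4.30e-08, and adjusted p = 0.550, 0.827 and 0.404 with an estimated correlation). Molting genes rose in 13 control and 17 CYP1A1 cases of 22 (13 and 17 adjusted over the list alone, with camera adjusted p = 0.00309 and 1.64e-09, and adjusted p = 0.418 and 0.138 with an estimated correlation). There was no call in the CYP1A2 strain, where 8 rose and 7 fell (8 and 7 adjusted over the list alone, with camera adjusted p = 0.757).

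The doses were also compared directly. Between 40 and 640 µM, 6891 genes differed in the control strain (3509 higher and 3382 lower at 640 µM), 7810 in the CYP1A1 strain (3911 and 3899) and 6389 in the CYP1A2 strain (3175 and 3214). In the control strain grl-21 (ZC168.5) rose from 6.30 ± 4.42 to 37.4 ± 13.9 FPKM, and col-120 (Y11D7A.11) fell from 114.2 ± 40.2 to 1.78 ± 2.33. Without replicate 1, grl-21 averaged 3.75 at 40 µM and col-120 0.445 at 640 µM. In the CYP1A1 strain fipr-24 (C37A5.8), of a family with predicted antimicrobial peptides, rose from 5.51 ± 1.08 to 75.5 ± 17.8, and col-60 (F22D6.10) fell from 303 ± 26.3 to 5.45 ± 8.90 (0.314 without replicate 3). In the CYP1A2 strain dao-6 (T05G5.12) rose from 2.82 ± 0.782 to 17.8 ± 5.42, and dao-4 fell from 134 ± 21.9 to 0.684 ± 0.278.

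To describe how far the strains shared the response, log2 changes at 640 µM were compared across the tested genes, which are not independent replicates. The correlation was 0.848 between the control and CYP1A1 strains, 0.831 between the control and CYP1A2 strains and 0.678 between the modified strains, with no libraries shared. In the control and CYP1A1 strains, 3566 genes rose in both, against 1365 for independent lists, 3938 fell in both, against 1516, and 210 were called in opposite directions. For the control and CYP1A2 strains the counts were 3502 (1328 for independent lists), 3787 (1472) and 232, and for the modified strains 3127 (1323), 3465 (1477) and 677.

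The modified strains were compared with the control strain in DMSO to describe how they differed without BaP. With a single strain for each modification, an effect of the human enzymes cannot be told from other differences between the strains. In the CYP1A1 strain 3516 genes differed, 2029 higher and 1487 lower, 479 of them at least 2-fold. All 6 vitellogenins were higher (median 2.1, adjusted p = 4.78e-11, and adjusted p = 0.0691 with an estimated correlation). The transcript of vit-5 (C04F6.1) measured 59.3 ± 16 against 7.80 ± 4.01 FPKM and that of vit-2 (C42D8.2) 365 ± 55.4 against 89.1 ± 25.8. The adult collagens col-7 (C15A11.5, 49.3 ± 19.2 against 6.93 ± 2.31) and col-119 (C53B4.5, 75.1 ± 21.2 against 13 ± 3.65) were higher. The collagen list held 58 higher and 28 lower (63 and 28 adjusted over the list alone, with camera adjusted p = 0.00267, and adjusted p = 0.744 with an estimated correlation). Molting genes were lower in 15 and higher in 2 of 22 cases (2 and 17 adjusted over the list alone, with median -0.58, adjusted p = 2.76e-07, and adjusted p = 0.217 with an estimated correlation). Levels of noah-2 were 32.5 ± 11.6 against 93.3 ± 19.2, and those of the hedgehog-related wrt-10 (ZK1290.8) 23.7 ± 12.9 against 79.3 ± 16. Ribosomal protein genes were lower by small amounts in 60 of 78 cases (0 and 67 adjusted over the list alone, with median -0.18, adjusted p = 1.68e-21, and adjusted p = 0.217 with an estimated correlation). Body wall muscle genes were higher in 10 of 13 (adjusted p = 2.76e-07, and adjusted p = 0.256 with an estimated correlation), such as the myosin myo-3 (K12F2.1, 87.7 ± 1.91 against 56.5 ± 2.85). Pharynx genes were higher in 10 of 14 (adjusted p = 8.61e-05, and adjusted p = 0.301 with an estimated correlation), such as phat-4 (T05B4.3, 92.3 ± 0.941 against 43.6 ± 5.84). Glucuronosyltransferases were higher in 19 and lower in 5 cases (22 and 7 adjusted over the list alone, with camera adjusted p = 0.00463, and adjusted p = 0.217 with an estimated correlation), with ugt-25 at 37.1 ± 2.09 against 20.4 ± 2.14. Of the other fixed genes, hsp-4 (log2 difference 0.24 ± 0.05) was higher and gst-4 (-0.36 ± 0.08) lower. Cytochromes P450 were not called (10 higher, 4 lower, 10 and 5 adjusted over the list alone, adjusted p = 0.815). The differences of cyp-35A2 (-0.03 ± 0.08, adjusted p = 0.872), cyp-35A5 (0.16 ± 0.13, adjusted p = 0.425), emb-8 (-0.03 ± 0.04, adjusted p = 0.725) and cep-1 (0.03 ± 0.07, adjusted p = 0.814) did not pass the test.

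The CYP1A2 strain differed from the control strain in DMSO at 2083 genes, 1279 higher and 804 lower, 90 of them at least 2-fold. The Wnt effector pop-1 (W10C8.2, chromosome I, 2822243 to 2830311) was higher at 87.6 ± 0.665 against 23.1 ± 0.699 FPKM (log2 difference 1.88 ± 0.05, adjusted p = 6.93e-17), with 3.91% of its exon bases inside another gene. Also higher were clec-52 (B0218.8, 27.7 ± 1.97 against 4.83 ± 0.237), the Mad-like transcription factor mdl-1 (R03E9.1, 40.9 ± 1.41 against 14.3 ± 1.31) and the stearoyl-CoA desaturase fat-7 (F10D2.9, 55.7 ± 5.69 against 24.8 ± 3.42). By contrast fbxo-11.2 (BE0003N10.3) was lower at 2.02 ± 0.205 against 30.3 ± 2.35. Oocyte genes were lower in 21 of 27 cases (0 and 22 adjusted over the list alone, with median -0.53, adjusted p = 1.02e-22, and adjusted p = 0.0838 with an estimated correlation). They included cpg-2 at 98.1 ± 3.47 against 166 ± 17.2 and puf-3 (Y45F10A.2), an RNA-binding protein gene of oocytes, at 28.7 ± 0.245 against 46.4 ± 3.32. Cytochromes P450 were higher in 18 and lower in 2 cases (19 and 3 adjusted over the list alone, with median 0.14, adjusted p = 3.92e-04, and adjusted p = 0.0838 with an estimated correlation), with cyp-35A2 at 39.8 ± 4.39 against 24.7 ± 0.272. The call of cyp-35A5 (5.46 ± 0.733 against 3.90 ± 0.749) ended without the filter, under quantile normalization, in voom, with only the compared groups in the fit, and without replicate 1 or 3 of either group. The call of gst-4 (64.2 ± 3.41 against 80.9 ± 2.46) ended without replicate 2 of either group. Ribosomal protein genes were lower in 24 of 78 (0 and 33 adjusted over the list alone, with median -0.11, adjusted p = 4.65e-15, and adjusted p = 0.332 with an estimated correlation). DNA repair genes were lower in 8 of 52 (0 and 12 adjusted over the list alone, with camera adjusted p = 3.09e-08, and adjusted p = 0.219 with an estimated correlation). Higher levels were found for ugt-25 (28 ± 1.47 against 20.4 ± 2.14) and hsp-4 (254 ± 7.81 against 218 ± 12). The differences of cep-1 (0.04 ± 0.07, adjusted p = 0.774) and emb-8 (0.03 ± 0.04, adjusted p = 0.697) did not pass the test. The count of changed genes was 1114 without control replicate 2 and 1379 and 1377 without replicates 1 and 3 of the CYP1A2 strain. Quantile normalization moved the split from 1279 higher and 804 lower to 997 and 1018.

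Set against each other in DMSO, the modified strains differed at 4305 genes, 2107 higher and 2198 lower in the CYP1A2 strain. There col-149 (B0024.1) was higher at 205 ± 22.3 against 26.3 ± 9.87 FPKM, and vit-5 was lower at 3.65 ± 1.92 against 59.3 ± 16. The differences of both modified strains from the control strain share its 3 DMSO libraries, which are too few to split. Their correlation across genes was 0.132 with a covariance of 0.0167, while unchanged groups simulated against the same controls gave 0.498 and 0.0269. Both strains were higher at 406 genes, against 155 for independent lists, and lower at 161, against 71, and 308 genes were called in opposite directions. The counts for independent lists do not allow for the shared controls. Since the covariance lay below that of the simulated groups, no agreement across genes was shown beyond what shared controls give.

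Whether the modified strains responded otherwise than the control strain was tested as a difference of responses. At 640 µM, 2690 genes responded otherwise in the CYP1A1 than in the control strain (1261 higher, 1429 lower) and 3102 in the CYP1A2 strain (1269 and 1833). At 40 µM the counts were 1333 (521 and 812) and 1228 (480 and 748). Cytochromes P450 were not called in any of these contrasts. At 640 µM 3 members responded higher and 4 lower in the CYP1A1 strain (adjusted p = 0.590), and 6 and 8 in the CYP1A2 strain (6 and 9 adjusted over the list alone, with camera adjusted p = 0.387). Glucuronosyltransferases responded lower in the CYP1A1 strain at 640 µM, 18 of 60 (3 and 22 adjusted over the list alone) with a median of -0.19 (adjusted p = 1.35e-04, and adjusted p = 0.163 with an estimated correlation). They were not called in the CYP1A2 strain (adjusted p = 0.388). Molting genes responded higher in the CYP1A1 strain, 15 of 22 (17 and 1 adjusted over the list alone) with a median of 0.76 (adjusted p = 8.27e-09, and adjusted p = 0.163 with an estimated correlation). In the CYP1A2 strain they responded lower, 16 of 22 (5 and 16 adjusted over the list alone) with a median of -0.71 (adjusted p = 1.95e-05, and adjusted p = 0.374 with an estimated correlation). Vitellogenins fell further in the CYP1A1 strain, all 6 with a median difference of -1.92 (adjusted p = 6.59e-09, and adjusted p = 0.143 with an estimated correlation). Here vit-5 responded by -5.85 against -2.97 in the control strain, a call that ended in voom. As given above, the vitellogenin and glucuronosyltransferase lists were already higher and the molting list lower in the CYP1A1 strain in DMSO. Those calls did not hold with an estimated correlation. For these 3 lists another response may therefore reflect another starting level, and need not mean other levels at 640 µM. Collagens responded higher in the CYP1A2 strain, 58 higher and 27 lower (63 and 31 adjusted over the list alone, with median 0.59, adjusted p = 2.83e-06, and adjusted p = 0.374 with an estimated correlation). Sperm genes responded lower there, 12 of 48 (0 and 18 adjusted over the list alone, with median -0.48, adjusted p = 2.83e-06, and adjusted p = 0.857 with an estimated correlation). The gene dao-4 responded by -1.42 against -4.23 on the log2 scale in the CYP1A1 and control strains (difference 2.81 ± 0.42, adjusted p = 1.19e-04). It responded by -7.80 in the CYP1A2 strain (difference -3.56 ± 0.42, adjusted p = 8.28e-06). Genes near 0 FPKM after exposure can fall no further, which limits how a difference of falls between strains can be read.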

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

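The tests below of whether the strain difference was already present in DMSO and the sorting of the splits by exchanged labels were chosen only after the result was seen, and the test of single libraries and the other splits of the samples were set before. Each result in this part was taken up because a test of the difference itself found that a modified strain responded otherwise to BaP than the control strain. At 640 µM, 2690 genes responded otherwise in the CYP1A1 strain and 3102 in the CYP1A2 strain, and at 40 µM 1333 and 1228 did.

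At 640 µM in the CYP1A1 strain, the response of dao-4 was higher than in the control strain by 2.81 ± 0.42 on the log2 scale, that of the chemoreceptor gene srw-85 (C25F9.1) by 2.12 ± 0.20 (2.3 against 0.18) and that of the collagen dpy-9 (T21D12.2) by 2.02 ± 0.29 (3.77 against 1.75). The response of vit-5 differed by -2.88 ± 0.49, that of nspb-8 (C01G12.10) by -2.84 ± 0.53 and that of nspb-12 (F09F7.8) by -2.66 ± 0.44. The calls of srw-85 and vit-5 ended in voom. In the control strain srw-85 averaged only 0.147 FPKM in DMSO (0.0913 without replicate 2) and 0.297 at 640 µM. In the CYP1A1 strain the means were 5.42 and 30.9. The log2(FPKM + 1) scale understates a change at such low levels, so its difference of responses is uncertain. In the CYP1A2 strain at this dose the collagens col-156 (F57B7.3, 3.02 ± 0.28) and col-54 (F33D11.3, 2.73 ± 0.30) and idpp-12 (W08E12.3, 2.96 ± 0.45) responded higher, and dao-4 (-3.56 ± 0.42) and the collagens col-63 (-3.19 ± 0.72) and rol-1 (Y57A10A.11, -3.07 ± 0.61) lower. For col-156 the responses were 1.73 against -1.29 in the control strain.

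At 40 µM in the CYP1A1 strain, gly-1 (F44F4.6, 1.84 ± 0.30), fbxo-11.2 (1.75 ± 0.21) and dos-2 (K10G6.2, 1.59 ± 0.37) responded higher, and col-146 (T06E4.6, -3.48 ± 0.50), nspb-12 (-3.35 ± 0.44) and col-80 (C09G5.5, -3.27 ± 0.31) lower. The call of gly-1 ended with a pseudocount of 0.1. In the CYP1A2 strain idpp-12 (3.16 ± 0.45), dct-5 (F07F6.5, 3.0 ± 0.54) and grl-4 (F42C5.7, 2.63 ± 0.48) responded higher, and kreg-1 (F53A9.2, -1.85 ± 0.41), col-181 (W03G11.1, -1.77 ± 0.53) and cpg-19 (C06G1.2, -1.58 ± 0.35) lower, where the call of col-181 ended under most alternatives.

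In the CYP1A1 strain, the genes with another response at 640 µM had a median absolute difference from the control strain of 0.392 in DMSO and 0.180 with BaP, a ratio of 2.17, and 1895 of them were called in DMSO against 726 at 640 µM. This is what would be seen if the response largely removed a difference present beforehand, which may be one of developmental timing. In DMSO the vitellogenin and collagen lists were higher and the molting list lower in that strain, but these calls did not hold with an estimated correlation (adjusted p = 0.0691, 0.744 and 0.217), so timing stays open. In the CYP1A2 strain the ratio was 0.470, with 877 genes called in DMSO and 2318 at 640 µM, which argues against a difference of that kind as the main cause there. Leaving out any 1 library kept at least 79.9% of the counts at 640 µM, which argues against a single deviating library, while differing exposure, metabolism by the human enzymes and other differences between the strains stay open and untested.

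With the strain labels permuted within each exposure, 1 of 100 splits, the real one, gave 2690 genes in the CYP1A1 strain at 640 µM (highest other 1909), and 1 of 100 gave 3102 in the CYP1A2 strain (highest other 1943). At 40 µM, 6 of 100 splits gave as many as the 1333 of the CYP1A1 strain (highest other 2519), and 4 of 100 gave as many as the 1228 of the CYP1A2 strain (highest other 4485). In each of these 4 sets the highest other split exchanged unequal numbers of strain labels with BaP and in DMSO, so it holds part of the difference between the strains itself. Splits with equal numbers gave at most 3 and 2 genes at 640 µM and 6 and 2 at 40 µM, but these mix the strains within groups and so widen the spread. Exchanging all 3 labels in DMSO alone, which measures the difference between the strains, gave 2961 and 3650 genes at 640 µM and 3953 and 4485 at 40 µM, and only the last of these was among the splits drawn. At both doses the splits therefore leave it open whether chance can be excluded.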

How the results depend on the processing

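Of these alternatives, voom and the restriction to protein-coding genes were chosen after seeing the data. Among 15 of the 16 counts of changed genes, every alternative stayed within 1.5 times the reported value. The exception was the CYP1A2 strain against the control strain in DMSO (2083), which ranged from 1114 to 1796 with 1 library left out, moving by more than 1.5 times without control replicate 2 (1114) and without CYP1A2 replicates 1 (1379) and 3 (1377). Fewer libraries lower the power, and why these libraries weigh more was not tested, so the cause was not tested. With the stricter filter, which tests fewer genes, the control strain at 640 µM gave 7536, and with sample weights 10447. The correlation of the responses at 640 µM fell with a pseudocount of 0.1 to 0.761 (control and CYP1A1), 0.748 (control and CYP1A2) and 0.618 (the modified strains), and that of the strain effects in DMSO rose to 0.274. Without the filter the correlation of the control and CYP1A2 responses was 0.811. Both settings give genes at low levels more weight, and the cause was not tested further. Of 278 list calls, 46 held with an estimated correlation, while fry called 408, of which 255 were shared, voom 275, median-of-ratios scaling 278 and the replicate block 280. Among 583 results for named genes, 10468 of 10601 alternative values were called or not called as reported, 129 lost the call and 4 gained it. None changed direction where either fit called the gene. Changes of sign in genes that neither fit called were not counted. Scaling moved the median of all genes by at most 0.0475. The only called list that changed sign with it was that of ribosomal proteins in the other response of the CYP1A1 strain at 40 µM, from 0.05 to -0.02 under quantile scaling. The labels number the replicates in each group, but the numbers did not pair the libraries. Deviations from the group means correlated by -0.0014 on average between libraries with the same number (from -0.157 to 0.0665) and by 0.0007 between others, and 8 of 27 libraries lay closest to their own number. With the replicate block the counts were 9768, 9760 and 9483 for 640 µM in the control, CYP1A1 and CYP1A2 strains, 5551, 5284 and 6861 for 40 µM, 6833, 7750 and 6327 between doses, 3414, 1978 and 4208 between strains in DMSO, and 2609, 3000, 1253 and 1168 for the other responses. Depth limits what can be said of genes under an FPKM of 1, among them ahr-1.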

Other observations

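In this part, the tests on the falls of collagen, vitellogenin, oocyte and sperm genes, the count of neighbouring genes without W03D8.13 and the values by locus were chosen only after the result was seen. Lipid metabolism genes moved in both directions at 640 µM BaP. In the control strain the fatty acid synthesis list held 11 higher and 8 lower of 21 (adjusted p = 0.293, not called). The desaturase fat-3 (W08D2.4) rose from 65.0 ± 5.26 to 174 ± 7.12 FPKM and the elongase elo-3 (D2024.3) fell from 93.8 ± 2.36 to 56.7 ± 2.89. Beta-oxidation genes numbered 21 higher and 11 lower of 42 and lipases 8 higher and 5 lower (9 and 5 adjusted over the list alone) of 19 (adjusted p = 0.293 and 0.670, not called). In both lists the median (0.11 and 0.25) and the mean (-0.03 and -0.19) differed in sign. The acyl-CoA dehydrogenase acdh-6 (C02D5.1) fell from 49.2 ± 0.750 to 4.3 ± 0.387 and the lipase lips-3 (F10F2.3) from 85.0 ± 6.23 to 7.13 ± 0.535, whereas lips-10 (F14E5.5) rose from 13.2 ± 1.38 to 90.8 ± 2.33. Lipid-binding proteins rose in 5 of 9 without a list call (adjusted p = 0.160). In the CYP1A1 strain the acyl-CoA synthetase acs-2 (F28F8.2) rose from 18.3 ± 2.31 to 118 ± 11.7, and in the CYP1A2 strain from 40.2 ± 4.34 to 181 ± 4.56. In DMSO the CYP1A2 strain had 16 of 42 beta-oxidation genes higher and 2 lower (20 and 2 adjusted over the list alone, with camera adjusted p = 1.48e-06, and adjusted p = 0.219 with an estimated correlation). It also had 8 of 21 fatty acid synthesis genes higher (13 and 1 adjusted over the list alone, with camera adjusted p = 1.38e-04, and adjusted p = 0.219 with an estimated correlation).

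Immune effectors were likewise mixed in the control strain at 640 µM. C-type lectins numbered 45 higher and 35 lower (46 and 35 adjusted over the list alone), and lysozymes and antimicrobial peptides 37 higher and 24 lower (37 and 25 adjusted over the list alone) of 77 (adjusted p = 0.554 and 0.143, not called). The gene fipr-24 rose from 5.45 ± 1.72 to 93.3 ± 2.94 FPKM, while the caenacin cnc-4 (R09B5.9) fell from 60.5 ± 3.91 to 8.60 ± 2.29 and the invertebrate lysozyme ilys-5 (F22A3.6) from 701 ± 19 to 236 ± 12. Targets induced by the insulin pathway factor DAF-16 rose in 7 of 14 and targets lowered by it in 3 of 9 (adjusted p = 0.132 and 0.397, not called). Argonautes, which carry small RNAs, numbered 7 higher and 10 lower of 20 (adjusted p = 0.293, not called), with hrde-1 (C16C10.3), needed for inherited silencing in germ cells, falling from 64.2 ± 2.70 to 42.9 ± 1.10.

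The collagen, vitellogenin, oocyte and sperm lists fell at 640 µM in the 3 strains, but none of these calls held with an estimated correlation (adjusted p from 0.0628 to 0.423), and 35, 33 and 37 collagens rose in the control, CYP1A1 and CYP1A2 strains. Over 4 lists, 3 strains and 4 ways of scaling the libraries, the highest median was -0.34. This argues against the choice among these scalings as the cause. All of them bring the libraries to a common level, so a change in total RNA could not be seen. A loss of germ cells of every stage would lower the germline list as far as the oocyte list. The oocyte median, however, lay far below that of the germline list. The difference was -1.77 in the control, -1.81 in the CYP1A1 and -1.66 in the CYP1A2 strain. Each had permutation p = 1e-05, 2-sided and the smallest these permutations can give. In these permutations, and in those of the collagens below, genes were shuffled between lists. Genes of a list are not independent replicates, so these p-values measure no spread between animals. The medians, known when this test was chosen, argue against such a loss as the whole cause. Slower development of exposed animals stays open, since the adult collagens col-7, col-19, col-62 and col-119 fell in every strain, with medians that differed from that of the other 135 collagens by -2.39 (permutation p = 0.0924), -4.43 (p = 0.0159) and -2.28 (p = 0.133) in the control, CYP1A1 and CYP1A2 strains, so the values may reflect younger animals, lower reproduction at the same age, or both.

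Single genes stood apart in a modified strain at DMSO, 40 µM and 640 µM alike: 146 genes in the CYP1A1 and 416 in the CYP1A2 strain were called one way at all exposures, of which 11 and 9, or 20 pairs of gene and strain, changed at least 2-fold each time. F56A4.3 (chromosome V, 2453414 to 2456147) measured 1.23 and 0.392 FPKM in the CYP1A1 and CYP1A2 strains in DMSO against 57.3 in the control strain, pop-1 was higher by 1.88, 2.02 and 2.02 in the CYP1A2 strain, and F14E5.8 (chromosome II, 8420098 to 8422186) by 1.92, 2.25 and 2.36 in the CYP1A1 strain, the first and last being named for this pattern after their values were seen. Overlap with another gene covered at least 50% of the exon bases in 5% of the pairs. This argues against reads shared with an overlapping gene as the cause for most of them. Reads shared with a paralog, as may be the case for clec-209, were not tested. Neighbours within 100 kb moved the same way by a median of 0.0181, at most 0.116 outside the locus of F56A4.3 and irld-35. This argues against a change of whole regions outside that locus. The 0.116 was that of clec-209 (Y19D10A.9, chromosome V, 2351676 to 2352932) in the CYP1A1 strain. This gene lies just over 100 kb from F56A4.3, so it counts as outside the locus only by a narrow margin. At the locus itself the value was 0.372 (0.407 in the CYP1A1 and 0.337 in the CYP1A2 strain), which leaves it open. Of the 20 pairs of gene and strain, 6 lay within 100 kb of another in the same strain. They were 2 of 11 in the CYP1A1 strain (as in 1139 of 10000 random draws) and 4 of 9 in the CYP1A2 strain (as in 13). But W03D8.13 is a noncoding RNA whose exon lies wholly inside pop-1, so its reads cannot be told from those of pop-1. Without it the count was 4, 2 of 11 (as in 1111 of 10000 draws) and 2 of 8 (as in 655). In both strains these were F56A4.3 and irld-35, so the strains do not give separate observations here. A slightly wider limit than 100 kb would add clec-209 (Y19D10A.9) to them in both strains, and such a limit was not tried. Whether stretches of chromosome differ between the strains stays open. The genes shared by both modified strains, clec-209 (Y19D10A.9), F56A4.3, F57A10.2 and irld-35 (F56A4.9), could also reflect a change in the control strain, which was not tested. For clec-209 (Y19D10A.9), the call in the CYP1A1 strain in DMSO ended in voom.

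The counts of changed genes between 2 groups of 3 libraries were set against the 10 possible splits, which are too few for a share under 0.05. In each, 1 split, the real one, gave as many. Every other split mixes libraries of both groups and so widens the spread. Low counts were therefore foreseeable there and do not measure chance. The real and the highest other counts were 9831 and 2, 9832 and 1, and 9553 and 1 for 640 µM against DMSO in the control, CYP1A1 and CYP1A2 strains, and 5624 and 1, 5373 and 2, and 6925 and 2 for 40 µM. Between the doses they were 6891 and 2, 7810 and 2, and 6389 and 2. In DMSO they were 3516 and 12 for the CYP1A1 and 2083 and 2 for the CYP1A2 strain against the control strain, and 4305 and 2 between the modified strains.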
